A study of Homo sapiens with 2 samples.

How the data were processed

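The deposited data are 1 scan of 1 two-colour Agilent array with the 2 samples of the series as its 2 channels. Per the labels, total RNA of untreated ECV304 cells (group control) was labelled with Cy5 and total RNA of HSV-2-infected ECV304 cells (group HSV-2 infected) with Cy3, after reverse transcription from a T7 primer. Each group has 1 sample, replicate 1, and no dye-swapped array is among the files used here. The sample titles say which sample was infected, whereas the series title names its groups as control and uninfected. The groups follow the sample titles. Those titles also word the cells differently, as human umbilical vein endothelial cells for the control and as endothelial like cells for the infected sample. The labels give harvest days 2, 4 and 6 for both groups and do not say whether these were pooled. Virus dose is not given in the sources used here.

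Per the file headers, the authors quantified the scan with Agilent Feature Extraction, version A.7.5.1, the tool also named in the submitters' processing notes. The deposited file gives each spot's intensity (mean and median pixel signal and local background, linear scale), and a processed intensity that, per the file headers, was background-subtracted and dye-normalized with LOWESS settings listed. Per the file headers, spatial detrending was off and the call of a spot as well above background used a multiplier of 2.6. The meaning of the dye normalization's numeric codes is not given in the sources used here. The deposited log10 ratio is that of Cy5 over Cy3 processed signal, which 99.99% of gene spots met within 0.01, and it was turned and put on the log2 scale here. The deposited p-value of each spot's ratio comes from the software's error model, per the file headers, and reflects technical error of 1 array; it was used only as an alternative filter. The authors' series matrix holds the processed intensity of each channel, on the linear scale, not centred. It differed from the scanner file's processed signal by at most 0.492%, which also fixed its direction: the control column is the Cy5 channel, with a median of 711, and the infected column the Cy3 channel, with a median of 711. No genome build or annotation release is named in the file, so no coordinates are given.

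Computed here with R 4.3.3 and limma 3.58.1: mean signals were corrected against the median local background with normexp and an offset of 50 on all 22153 spots, and log ratios were normalized within the array by loess with control spots at weight 0. All ratios are log2 of infected over control. The 29 gene spots that the software marked as outliers were left out and saturated spots were kept. Spots of a probe were averaged, then probes of a gene, among probes well above background in both channels (over 50% of their spots); 19167 genes entered. Gene names in the file date from the array's design. They were updated through a RefSeq gene table of GRCh38.p14, used for names only: of 20173 gene probes, 13318 (66.0%) matched a gene by current symbol, by an older symbol with 1 match or by accession, and the others kept the file's name.

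With 1 sample per group there is no test between the groups and no p-value across genes. Genes were called lower or higher by a size of 2-fold. A list of genes was described by its median and the percentile of that median among 10000 random lists of the same size, drawn from named genes in 20 bins of mean intensity; this describes 1 array. The pooled SD between spots of probes with 3 or more usable spots was the technical spread. For genes above background in 1 channel alone, the bright channel was set against the higher of the dim channel's own signal and the lowest signal well above background there, after loess and scaling of the channels' intensities. These bounds are open to dye bias.

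The choices fixed before the data were examined were the groups, the 2-fold size, 25 gene lists, the alternatives and the rule for named genes. By that rule the text names the 15 genes with the largest ratios in each direction that had a gene symbol, were unsaturated, had all probes on the same side of 0 and were past 2-fold in the software's ratio too, which 241 lower and 0 higher genes met. It also names 5 genes per direction with the largest bounds among those seen in 1 channel, up to 4 members of each list with the largest ratios (up to 6 where more passed 2-fold), and the common reference genes. A few genes that the rule selects are not reported here. RPL10 is not on the list of ribosomal proteins as fixed. A further 9 lists were written after some values had been seen. They are named with their results in the closing section.

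The method was tested on simulated data made from this array's control channel, its dye curve and its spot noise, with 200 of 20023 probes changed. Of 50 probes lowered by 2 on the log2 scale, 80% were called lower, and of 50 lowered by 1.5, 56%. Of 50 raised by 2, 96% were called higher, and of 50 raised by 1.5, 78%. The simulation took all signal above the level of the negative control spots as that of the probe's own transcript. For probes with other signal, which the closing section weighs, these rates are too high. Among 19823 unchanged probes 0 were called. The simulated noise was that between spots and held no dye effect of single probes, labelling or culture variation, so this 0 does not bear on those. Of 40 random lists of 30 genes, 38 lay inside the 95% range. These were drawn from the same named genes as the lists they were set against, so this checks the procedure only.

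Alternatives to the background correction, the offset, the spot signal, the normalization, the filter on dim probes, saturated spots, the probe used for a gene, the size threshold and the matching of random lists were computed, and the closing section gives their effect. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The number of arrays, 1, limits the precision: signal was well above background for over 99% of gene spots in each channel, yet no value has an error from a repeat culture.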

Results

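Gene expression in ECV304 cells infected with herpes simplex virus 2 (HSV-2) was set against that in untreated ECV304 cells on 1 two-colour oligonucleotide array. ECV304 is a human line first described as spontaneously transformed umbilical vein endothelial cells and later shown to derive from the T24 bladder carcinoma line. RNA of the control culture was labelled with Cy5 and RNA of the infected culture with Cy3, so each group is 1 sample and there is no replicate culture or dye-swapped array. The labels list harvests on days 2, 4 and 6 for both groups without saying how they were combined. The array held 21073 gene spots and 1080 control spots. Of the gene spots, 99.7% in the control channel and 99.5% in the infected channel were well above background, and 8 and 10 were saturated. No test between the groups was possible, so differences are described by size, with the error between replicate spots of a probe. This error was 0.096 on the log2 scale (pooled SD, 152 probes with control probes included, 1829 spots), and 0.080 over the 100 gene probes alone (994 spots). This error covers neither culture, labelling nor dye.

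The comparison asked which host transcripts differed between infected and control cells. Nearly all sizeable differences were lower in the infected channel: 323 of the 19167 genes measured in both channels were lower by 2-fold or more and 1 was higher. The lower genes with the most negative ratios included EIF4G2, a translation initiation factor related to eIF4G, at a log2 ratio of -2.80 (6.98-fold lower), and RBM39 (RNPC2 in the file), a splicing coactivator, also at -2.80. DYRK1A, a dual-specificity kinase, lay at -2.56, MATR3, which encodes the nuclear matrix protein matrin 3, at -2.54, and CLK1, a kinase of SR splicing factors, at -2.33. RPLP0, a ribosomal stalk protein and common reference gene, lay at -2.31 (4.96-fold lower). LDHB, a lactate dehydrogenase subunit, lay at -2.17, PSMB4, a proteasome subunit, at -2.15, and CANX, which encodes the endoplasmic reticulum chaperone calnexin, at -2.12. The mitochondrially encoded ND4L lay at -2.10, HSPCA, a cytosolic HSP90 gene under its older name, at -2.08, and RPL10, a ribosomal protein, at -2.06. BTF3P11 at -2.43 and PABPC3 at -2.42 are uncertain, since they share sequence with a parent gene or close relatives that their probes could detect. The single gene past 2-fold in the other direction, named after its value was seen, carries only the clone name I_932883 and lay at 1.25 (the control was at 0.421 of the infected value).

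**Figure D1:**
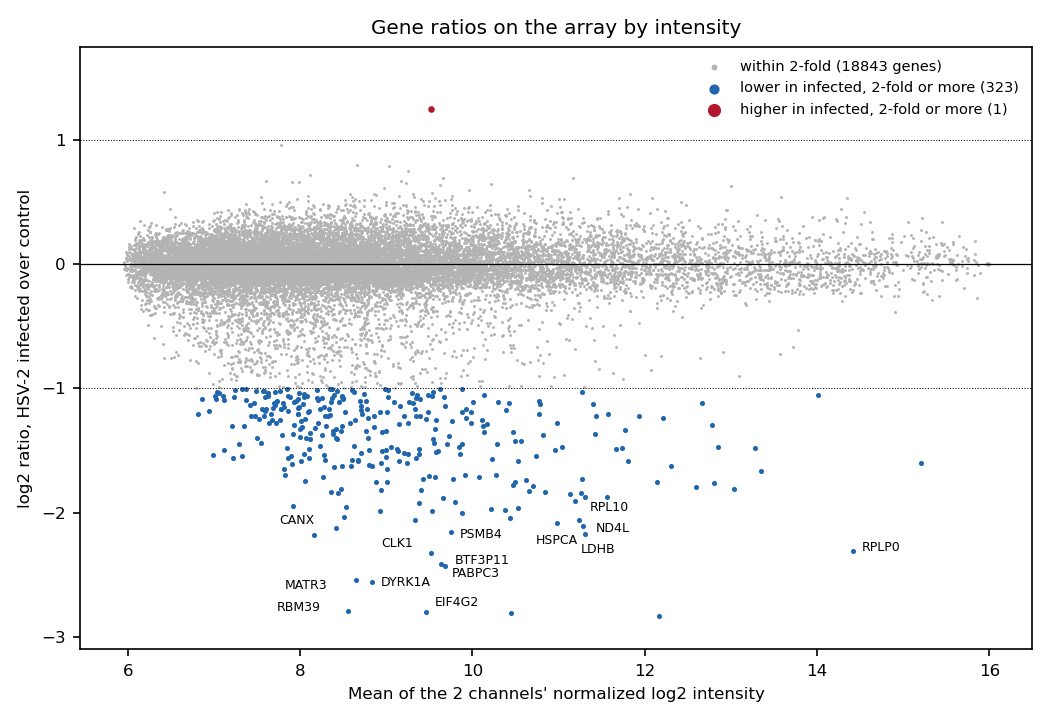
Log2 ratio of HSV-2 infected over control (vertical axis) against the mean normalized log2 intensity of the 2 channels (horizontal axis), 1 point per gene, with named genes labelled and dotted lines at 2-fold. The 323 genes lower by 2-fold or more (blue) spread over most of the intensity range, and 1 gene (red) was higher by as much.

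Over all genes the median log2 ratio was -0.01 and 94.9% lay within 0.5 of 0. At that smaller size the difference between directions held, with 913 genes at -0.5 or less and 56 at 0.5 or more. All 323 lower genes were also past 2-fold in the ratio that the scanner software wrote, and that ratio alone put 506 genes lower and 9 higher. With no normalization between the dyes, 213 were lower and 2 higher.

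Replicate spots gave the only measured error, and only for probes spotted more than once. Each named gene with the most negative ratios, from EIF4G2 to RPL10, had 1 probe with 1 spot. The ratios of those genes therefore have no replicate error of their own. Only 1 replicated gene probe had a mean of -1 or less. Of 100 gene probes with replicate spots, 11 had a mean log2 ratio of -0.5 or less, every spot of these 11 lay below 0, and 0 probes had a mean of 0.5 or more. BAZ1A, a chromatin remodelling subunit, was at -1.16 ± 0.12 (SD, 10 spots). EIF5B (IF2 in the file), which joins the ribosomal subunits at initiation, was at -0.90 ± 0.16, and HIF1A, the oxygen-regulated transcription factor subunit, at -0.79 ± 0.072, each over 10 spots. These 3 were picked from the replicated probes after their values were seen.

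**Figure D2:**
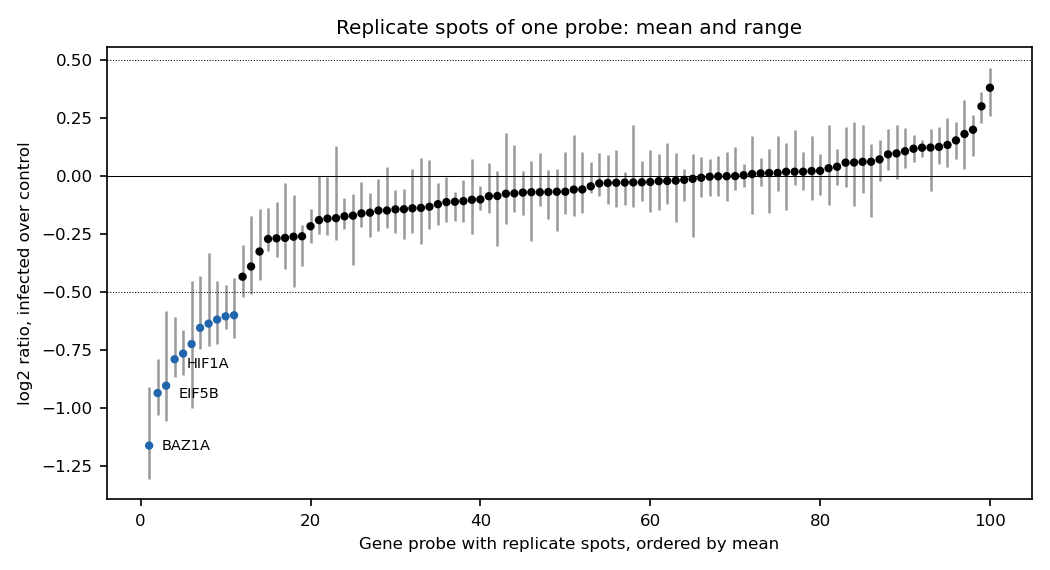
Mean (point) and range (line) of the log2 ratio of HSV-2 infected over control over the replicate spots of each of 100 gene probes, ordered by mean, with dotted lines at 0.5 above and below 0. The 11 probes at -0.5 or less (blue) have every spot below 0, and no probe has a mean above 0.5.

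Among cytosolic ribosomal proteins, 13 of 55 measured genes were lower by 2-fold or more, 0 were higher and 42 lay between. RPLP0 was followed by RPL5 at -1.89, RPL6 at -1.73, RPL3 at -1.66, RPL11 at -1.63 and RPL7 at -1.58, while RPS21 lay at 0.36 and RPL13 at 0.30. The list's median of -0.35 lay below all of 10000 random lists matched on intensity (95% range -0.07 to 0.04), and stood at -0.18 with no normalization, when the median of all genes was 0.16. In the oxidative phosphorylation list 3 of 42 genes were lower: ATP5F1B (ATP5B in the file) at -1.96 and ATP5F1A (ATP5A1) at -1.87, the catalytic beta and the alpha subunit of ATP synthase, and NDUFS1 of complex I at -1.49; NDUFA9 lay at -0.98 (-1.20 in the software's ratio). Its median of -0.09 was at percentile 0.35 of the random lists (34.92 over the upper 50% of intensity), and stood at 0.07 with no normalization. Among the hypoxia and glycolysis genes, LDHA at -1.44 and TPI1 at -1.07 (-0.87 with no normalization) were lower, HIF1A lay at -0.79 (-1.12 in the software's ratio) and BNIP3L at -0.94 (-1.08), though the 2 probes of BNIP3L disagreed (-1.93 and 0.05). The median of those 31 genes was -0.06, at percentile 7.05 (2, below the 95% range, with the median signal).

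No antiviral gene was higher by 2-fold, but only 1 of all 19167 measured genes was, so this is not particular to them. Of all genes, 1.685% were lower by 2-fold or more, the share beside which the single lower genes of these lists stand. Of 44 interferon-stimulated genes, TRIM22, an antiviral ubiquitin ligase, was lower at -1.28, and RSAD2 (viperin; cig5 in the file) lay at -0.90, GBP1 at -0.64 and GBP2 at -0.57. With a normexp offset of 0 and in the software's ratio 3 of the 44 were lower, with RSAD2 at -1.35 and -1.34 and GBP1 at -1.63 and -1.66. The highest value on this list was 0.44. The median of -0.08 was at percentile 0.90 (2.95 with an offset of 0 and 17.15 over the upper 50% of intensity, both inside the 95% range), and stood at 0.10 with no normalization against 0.16 for all genes. Of 24 genes of interferons, their receptors and virus sensing, TLR2, a receptor of microbial surfaces, was lower at -1.41, while TBK1 lay at -0.71, MYD88 at -0.49 and IFNGR1 at -0.25, with a median of -0.02 at percentile 42.3. Of 43 NF-kB targets, cytokines and chemokines, NFKB1, the gene of the p105 and p50 subunits, was lower at -1.02 (-0.83 with no normalization), and SOD2 lay at -0.71, IL32 (NK4) at 0.40 and IL18 at -0.34. That list's median was -0.01, at percentile 54.5.

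Antigen presentation genes were split. B2M, the light chain of MHC class I, was lower at -1.53, PSME1, a proteasome activator subunit, at -1.53, HLA-G at -1.35 and HLA-F at -1.26. HLA-B lay at -0.90, while HLA-C lay at 0.12 and NLRC5 at 0.43 (these 3 were named after their values were seen). Probes of MHC class I genes can share sequence, so the single genes are uncertain. Of 26 genes 4 were lower and 0 higher, against 0 to 3 lower in 95% of the random lists, and the median of -0.03 lay at percentile 33.7.

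In the stress lists, XBP1 and ATF4, transcription factors of the unfolded protein and integrated stress responses, were lower at -1.70 and -1.32. CEBPG lay at -0.51 (its 2 probes at -0.90 and -0.12) and the chaperone gene HSPA5 at -0.28, and the median of the 24 genes was -0.05 at percentile 16.5. Of the 25 matched heat shock and oxidative stress genes 0 passed 2-fold, and 1 did with an offset of 0 and in the software's ratio: DNAJA1 lay at -0.85, TXNRD1 at -0.80 (-1.12 and -1.10 there), HSP90AB1 (HSPCB) at -0.56 and HSPB1 at 0.36, with a median of -0.04 at percentile 19.4. The list as fixed also holds HSP90AA1, to which no probe was matched. HSPCA, the cytosolic HSP90 gene at -2.08, kept its older name and is not among the 25, so the count of 0 leaves it out. DDB2, a DNA damage sensor, was the lower gene among 18 p53 targets at -1.47, FAS lay at -0.48, ZMAT3 at -0.43 and SESN1 at -0.42, and the median was -0.05 at percentile 18.7. Of 30 apoptosis regulators 0 passed 2-fold, with CASP1 at -0.50, DIABLO at -0.48, TRADD at 0.39 and MCL1 at -0.25 and a median of -0.06 at percentile 7.36. Of 33 immediate-early and AP-1 genes 0 passed 2-fold, with FOS at -0.90, DUSP1 at -0.85, KLF4 at -0.66 and SRF at 0.44 and a median of 0.01 at percentile 75.2. With an offset of 0, 3 of them were lower (FOS at -1.01, DUSP1 at -1.16 and KLF4 at -1.21), and in the software's ratio 2 (DUSP1 at -1.12 and KLF4 at -1.19).

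Among 35 DNA replication genes, PCNA, the sliding clamp of DNA polymerase, was lower at -1.72 and TYMS, thymidylate synthase, at -1.70, while FEN1 lay at -0.38 and E2F2 at 0.37; the median was 0.00 at percentile 67.2 (99.05 over the upper 50% of intensity). Of 35 mitotic genes, TOP2A, a DNA topoisomerase, was lower at -1.65, TTK lay at -0.56 (-1.12 in the software's ratio), NUSAP1 and CCNB1 at -0.49, and the median was -0.07 at percentile 2.9 (2.12, below the 95% range, in the software's ratio). Of 22 histone genes 0 passed 2-fold, with H3-3B at -0.99 (-1.01 in the software's ratio), H1-4 at 0.44, H2AC6 at -0.43 (2 probes, -0.77 and -0.09) and H2AC18 at 0.29 and a median of -0.04 at percentile 20.6. The 20 genes of PML bodies, chromatin and nuclear factors that meet the viral genome had a median of -0.11 at percentile 1.66 (0.07 with no normalization against 0.16 for all genes), and lay inside the 95% range over the upper 50% of intensity (percentile 3.55) and with the brightest probe of a gene (4.8). None of these 20 passed 2-fold: HDAC2 lay at -0.61, ATRX at -0.38, SP100 at -0.26 (2 probes, -0.52 and -0.01) and MRE11 at -0.22.

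None of 26 HSV entry receptor and heparan sulfate genes passed 2-fold. The highest were NECTIN1, an entry receptor for the HSV glycoprotein D, at 0.23, and EXTL3 and GPC1 at 0.22, with HS3ST2 at 0.20. The median of 0.08 was at percentile 98.99, but at 93.6, inside the 95% range, with median centring alone and with no normalization, and stood at -0.03 (percentile 43.55) over the upper 50% of intensity. Of 28 cholesterol synthesis and uptake genes 0 passed 2-fold, with FDFT1 at -0.72, MVD at 0.34, ACAT2 at -0.29 and SCD at 0.27 and a median of -0.01 at percentile 52.6. Of 22 coagulation and fibrinolysis genes 0 passed 2-fold, with THBS1 at -0.41, F3 at -0.17, F2R at -0.16 and PLAUR at 0.15 and a median of -0.03 at percentile 34.0. Of 36 extracellular matrix and epithelial-mesenchymal genes 0 passed 2-fold, with TGFB2 at 0.40, COL4A2 at 0.29, TGFB1 at 0.25 and SPARC at -0.21 and a median of -0.01 at percentile 53.6.

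Common reference genes did not hold one level. RPLP0, B2M, YWHAZ at -1.26 and TFRC, the transferrin receptor, at -1.03 (-1.70 in the software's ratio and -0.88 with no normalization) were lower, whereas ACTB lay at -0.11 and GAPDH at 0.16. With no normalization, when the median of all genes was 0.16, ACTB lay at -0.04 and GAPDH at 0.37. The median of the 18 genes was -0.15, at percentile 0.06 of the random lists, and -0.04 with no normalization.

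Cell type markers were measured in the same way. The 28 endothelial markers had a median of 0.01 at percentile 75.8. S1PR1 at -1.26 was lower, with another probe, kept under its older name EDG1, at -0.41, while MMRN1 lay at -0.87 (-1.17 in the software's ratio), PECAM1 at -0.47 and ENG at 0.33. The 26 urothelial and simple epithelial markers had a median of 0.00 at percentile 64.9, with CLDN4 at -0.28, UPK3A at 0.23, DSP at -0.22 and EPCAM at -0.21. The 14 fibroblast and smooth muscle markers had a median of -0.07 at percentile 12.6, with ACTA2 at -0.60, MYH11 at 0.38, CNN1 at 0.34 and COL1A1 at -0.18. Of 19 blood cell markers 2 were lower, among them HBB, beta-globin, at -1.05 (-0.98 with no normalization), while LYZ lay at -0.52 and HBA1, alpha-globin, at 0.33. Their median was -0.05 at percentile 22.9.

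**Figure D3:**
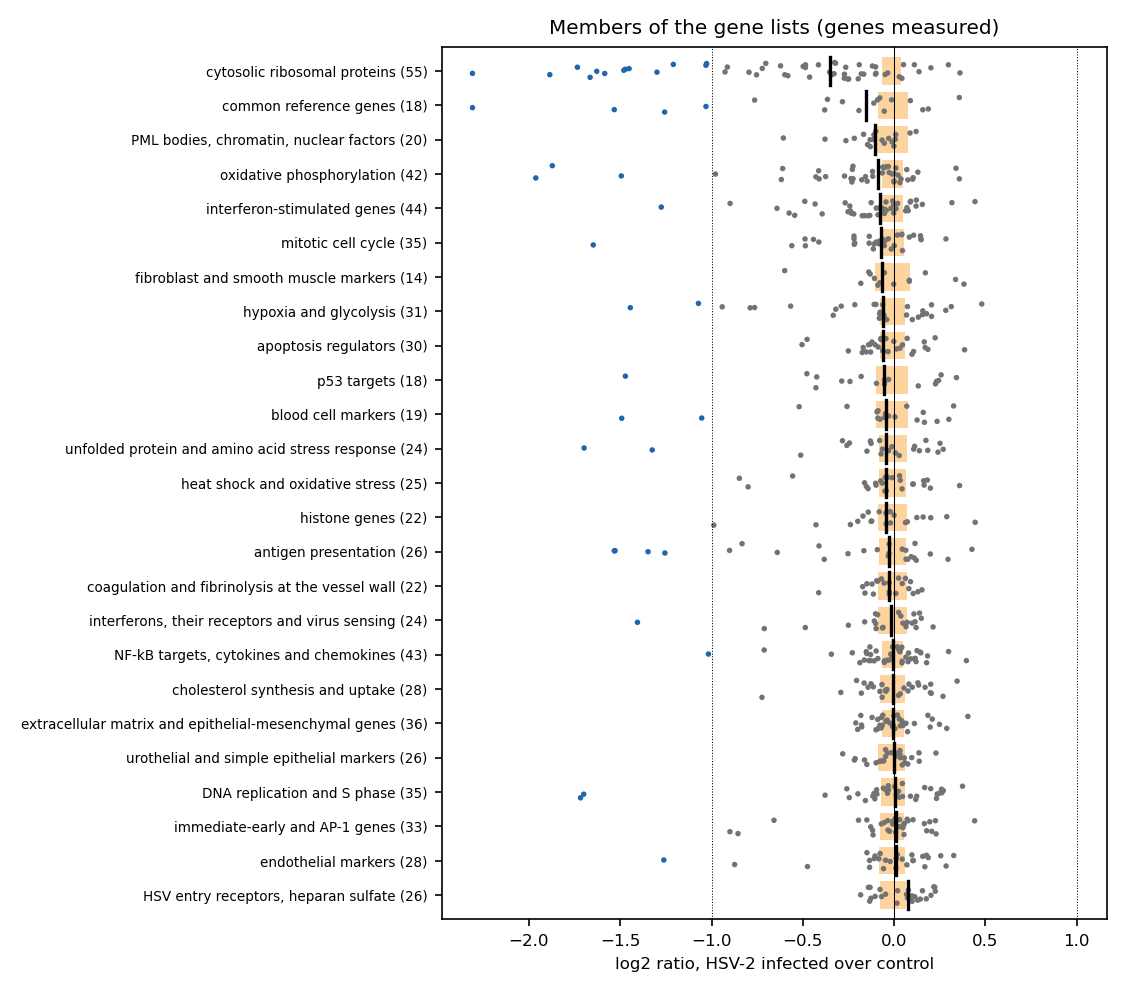
Log2 ratio of HSV-2 infected over control (horizontal axis) of every measured member of the 25 gene lists, with the number measured in brackets; blue points are lower by 2-fold or more, black bars are list medians and orange boxes the 95% range of medians of 10000 random lists matched on intensity. The cytosolic ribosomal proteins have the lowest median at -0.35, and no member of any list is higher by 2-fold.

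Genes well above background in only 1 channel were few and dim. In the control channel alone 56 genes were above background, and in the infected channel alone 24. The bounds were small. CREBL2 was at least 1.32-fold higher in the control channel, BTN2A1 at least 1.28-fold, G3BP2 at least 1.27-fold, and IFNA21 and UMPK at least 1.19-fold. In the infected channel, AFAP1 (AFAP in the file) was at least 1.2-fold higher, and KCNC1 and ANKS1B at least 1.12-fold. For ADAMTS8 (1.15-fold) and FANCA (1.11-fold) the control channel's own signal set the value, so it is the observed ratio. The log2 values of KCNC1, ANKS1B and FANCA (0.1552 to 0.1651) lay near the 95% span of spot error, 0.1885 over all replicated probes and 0.1576 over gene probes. The software's significance call is less strict than its background call. By it, 12 genes were above background in the control channel alone and 0 in the infected channel alone.

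Across the 25 lists, 5 medians lay below the 95% range of the random lists and 1 above it; the 1 above was inside the range with median centring alone and with no normalization. Because dye and infection went together on 1 array, a lower value in the infected channel is also a lower value in Cy3. The array cannot separate them.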

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

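The tests of control spots, of classes of intensity and of genes with 2 probes were chosen after the values had been seen, and the counts under other normalizations were fixed before. The signals in this paragraph come from control spots, which the comparison of genes does not use. Spots of the control sequence Pro25G were higher in the infected channel: the mean log2 ratio was 2.10 for Pro25G-01, 1.54 for Pro25G-02 and 1.03 for Pro25G-03, against -0.02 for the negative control spots. The dimmer eQC control spots, under 37 names, had a median log2 ratio of 0.92 (0.70 to 1.09), and of 2.51 in the software's ratio, with the control channel near background. The 3 brightest eQC names had a median of 0.02, and the 10 E1A spike-in names a median of 0.00 (-0.12 to 0.25). What was added to each labelling is not given in the sources used here, so no explanation is offered for these values.

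The one-sided set of lower genes is the first of 3 patterns weighed. A dye trend with intensity was weighed as its whole source. Under loess, median centring, no normalization and the software's ratio, at least 98.3% of the 2-fold genes were lower. These scalings moved the median of all genes only between -0.01 and 0.16, so that share had little room to fall. Each of 5 classes of intensity held lower genes (11, 51, 88, 93 and 80), from 0.29% of the dimmest class to 2.43% of class 4. Class medians, which loess sets near 0, lay between -0.0171 and 0.0019. The lower genes thus departed from most genes of like intensity, which a trend with intensity alone would move together. Probes that differ on their own, whatever their gene, were weighed as the whole source too. For 39 genes with 2 probes, the first by order of probe name was at -0.5 or less. The second was as low in 38.5% of these (Wilson 95% interval 24.9 to 54.1), against 5.72% of all probes of such genes. In either order, 15 genes had both probes low, against 2.6 expected without a relation between the probes. This goes against such probes as the whole source only where the 2 probes differ in sequence. Probe sequences are not given in the sources used here, so that could not be checked. Still, 64 of the 79 genes with a low probe had only 1 low probe, and the log2 ratios of the 2 probes correlated at r = 0.37 over 822 genes, which are not independent replicates, so a part of single lower genes may belong to the probe. Infection and dye cannot be told apart here, since 0 dye-swapped arrays of this RNA are at hand.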

How the results depend on the processing

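Of the alternatives below, all were fixed before the data were examined. The direction of the 54 named genes past 2-fold held under each of the 11 alternatives that measured them. Each alternative reuses the same spots in which these genes were picked for their size, so a kept direction says little about robustness. Of these 54, 47 stayed past 2-fold with no normalization, 52 with no background subtraction and 53 with median centring alone; over the upper 50% of intensity 43 were measured and all 43 stayed past it. The counts of genes past 2-fold depended on the scaling, always with most genes lower. Normexp with an offset of 0 gave 518 lower and 7 higher, no normalization 213 lower and 2 higher, and the software's ratio and the series matrix 506 lower and 9 higher each. A 1.5-fold size gave 771 lower and 19 higher, and a 3-fold size 78 lower and 0 higher. A smaller offset gives larger ratios to dim spots by construction, and the cause of the other differences was not tested. The 323 lower genes stayed lower by 2-fold under the software's ratio (323) and offset 0 (323), and 213 of them with no normalization. The first 2 settings use the same spots and put more genes past 2-fold (506 and 518 lower), so that all 323 stayed there says little about robustness. Over the upper 50% of intensity, 2 in place of 5 lists lay below the 95% range, with fewer genes measured; under the other alternatives 4 to 7 did. By the significance call, 12 in place of 80 genes were above background in 1 channel, all 12 in the control channel. No normalization moved the median of all genes to 0.16 and turned the sign of 21 of 34 list medians, 5 of them of lists outside the 95% range: interferon-stimulated genes 0.1036, oxidative phosphorylation 0.0721, PML bodies and nuclear factors 0.0671, erythroid-restricted genes 0.0427 and genes abundant in epithelial lines 0.0931. Relative to all genes, each of the 12 lists outside the 95% range kept its sign there, under median centring and under the software's ratio, but the HSV entry and heparan sulfate list left the 95% range under the first 2. Over the upper 50% of intensity the median of the HSV entry and heparan sulfate genes was -0.0266; the cause was not tested. Under the 10 alternatives other than no normalization, 0 to 7 of the 34 list medians changed sign. No paired analysis was possible because each group has 1 sample and the result comes from no test. Signal over background limits the results: over 99% of gene spots were well above it in each channel, but so were 96.2% of 52 tissue-restricted genes, so a spot above background need not show its own transcript.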

Other observations

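In this part the lists were written, and all tests chosen, after some values had been seen, so none is independent evidence of a direction. The lower genes extended to groups not on the lists fixed before. All 9 measured mitochondrially encoded genes were at -0.65 or less and 6 were lower by 2-fold or more, among them COX1 at -1.87, ND5 at -1.79 and ND2 at -1.58. The spot of ND6, also among the 6, was saturated in the control channel, so its ratio is only a bound; the median of the 9 was -1.58, and -1.32 with saturated spots left out. Of 36 genes of translation factors and poly(A) binding, 8 were lower and 0 higher, with EIF4A1 at -2.003, EIF4A2 at -1.98, EIF1 (SUI1 in the file) at -1.85 and PABPC1 at -1.84 after EIF4G2, and a median of -0.31. Of 46 splicing factors, 8 were lower and 0 higher, with SRSF2 at -1.92, SRSF11 at -1.60 and both probes of SRSF3 low (-1.49 and -1.43), and a median of -0.23. Of 30 proteasome subunits, 5 were lower and 0 higher, with PSMB3 at -1.82, PSMD14 at -1.58 and PSMC5 at -1.22, and a median of -0.25. Each of these 4 medians lay below all 10000 random lists.

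Within these groups the ratios were uneven, which is the next pattern weighed. A loss shared alike by all abundant host transcripts would put other abundant genes as low, and the 33 genes abundant in epithelial cell lines had a median of -0.0955 (members' SD 0.405), with TUBA1B at -1.504, TUBA1C at -1.17 and TMSB10 at -1.11 among 3 lower and 30 between; with no normalization 1 was lower, with TUBA1C at -0.96 and TMSB10 at -0.90. That median is above the -0.35 of the ribosomal proteins by less than the members' SD, the rule used here. The SD describes the spread of single genes and not the error of a median, so this rule cannot decide. The medians show a smaller shift for these genes, but not whether their own transcripts fell less. Signal that does not come from a probe's own transcript may draw many ratios towards 0: 96.2% of 52 genes restricted to tissues such as eye, testis and pituitary were well above background in both channels, against 14.8% and 6.8% of the negative control spots. The 50 of these that were measured had a median of 0.02, with GNAT1 at 0.54 and 0 lower by 2-fold. An uneven loss of host RNA under infection, dye and this background signal therefore remain open together.

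Red-cell genes form the remaining pattern. Of 31 erythroid-restricted genes 8 were at -0.5 or less (0 to 5 in 95% of the random lists), with a median of -0.11 at percentile 0.32: HBG2 lay at -1.48, RHAG at -1.11, HBB at -1.05 and EPB42 at -0.89. Red-cell RNA in the control sample should lower all of its abundant transcripts, yet 3 of 8 were at -0.5 or less, with ALAS2 at -0.13, SLC4A1 at -0.25 and HBA1 at 0.33. Whole blood is a candidate source only if white-cell genes are low as well, and 3 of 43 were at -0.5 or less against a mean of 2.57 in random lists (median 0.00, percentile 69.5), while the 16 platelet genes had a median of 0.07 at percentile 96.4 with F13A1 at -0.87 and GP9 at 0.53. Since probes of genes that should be silent gave signal too, a ratio near 0 excludes neither source, and both stay open. Globin probes can also share sequence among the globin genes. The blood cell markers fixed before already held 3 of these erythroid genes, HBA1 and HBB among them, 5 of the white-cell genes and 2 of the platelet genes.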
